A study of Mus musculus with 17 samples.

How the data were processed

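Hippocampal RNA of 17 male mice was hybridised to Affymetrix mouse expression arrays, 1 animal per array. Groups were taken from the sample labels: 8 animals sleep-deprived for 5 h by gentle handling and 9 undisturbed animals, all handled daily for 6 days beforehand, with an age of 2 months in the sample labels and a range of 2 to 4 months in the growth protocol. Dissections alternated between the groups, per the labels' protocols, and no batch or scan date was used here. The replicates are separate animals.

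The deposited values were log2 signals, 1 per probe set and array. They were summarised and normalized with RMA, and the affy package was used, per the submitters' processing notes. The log base was inferred from the range of the values, which ran from 2.90 to 14.6. The order of steps, software versions and any filter are not given in the sources used here. RMA models the perfect-match probes together across arrays and equalises their distributions, so that a change shared by most genes cannot be seen, and dim probe sets show compressed differences. No array had a value missing, and no pair of arrays held identical values: the highest correlation between arrays was 0.998. Arrays have no sequencing depth, and their number limits the precision. The 25 and 75 percentiles of single arrays lay between 4.54 and 4.67 and between 8.23 and 8.35.

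Of 45101 probe sets, 64 were manufacturer's controls and were left out of all tests of genes. The remaining 45037 were tested as probe sets. Gene symbols came from the platform annotation: 34945 probe sets carried 1 symbol, 932 carried several and were not named, and 9160 carried none. Symbols were compared through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which matched 34741 probe sets and changed 0 symbols. That table was used for names only, and no coordinates are given. Each of the 18193 genes was represented by the probe set with the highest mean over the 17 arrays. For 9010 genes there was more than 1 probe set.

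The comparison was fitted in limma 3.58.1 under R 4.3.3 as a group mean model with lmFit and eBayes on the deposited log2 values. The p-values were adjusted by the Benjamini-Hochberg method over all genes, or over all probe sets, with a threshold of 0.05. All adjusted p-values of single genes and probe sets are from limma. Confidence in a difference is given by its moderated standard error (SE). Before the data were examined, 29 gene lists were fixed for hippocampal activity, stress, metabolism, synapses, the clock and cell types. Of their 766 entries 682 were measured through a probe set with a single symbol. Lists were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 29 lists. Of the 13 lists that passed with the preset correlation none passed with an estimated one, where the smallest adjusted p was 0.28 and 4 lists had an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 6 lists in one direction and 22 in either direction. After the data were seen, an exact two-sided permutation test of each list's mean per array over all 24310 assignments of 17 arrays to groups of 8 and 9 was added. It keeps the correlation between genes, it is adjusted over the 29 lists, and 7 lists passed it. Like fry, it does not compare a list with other genes, so a shift shared by genes of similar signal can make a list pass. List medians were also placed among 10000 random lists of the same size matched in 20 bins of mean signal.

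Genes were named by a rule fixed before the data were examined. It took the 15 largest increases and the 15 largest decreases among called genes with all 8 sleep-deprived arrays on one side of the undisturbed mean, skipping clone and predicted-gene names. It took up to 4 members of each list by adjusted p with called members against the list's direction, and 26 genes fixed by name, of which 24 were measured. Hnrnpd, Mvd, Nsdhl, Cry2, Ciart, Ttr, Tfrc, Dtna, Rprd2, Kif1b, Sc5d and Hspa4 lie outside that rule and were chosen after their values were seen.

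The alternatives were filters on mean signal, quantile normalization, median centring, other rules for several probe sets of a gene, eBayes with trend and robust options, array weights and a replicate block. Covariates for RNA quality (the signal of the 3' minus the 5' control probe sets of Gapdh and actin) and for choroid plexus markers were tried as well. An unequal-variance test, an exact rank-sum test, stricter thresholds and each array left out in turn completed the planned set. Cyclic loess between arrays, the first residual principal component as a covariate and the exact permutation of list means were added after seeing the data.

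The gene fit and the list test were tested on simulated data with the real genes' means and standard deviations for this comparison, on 18193 genes with 200 changed. Of 100 genes changed by 1.2-fold 73 were called, of 100 changed by 1.5-fold 97 were called, and 4 of 17968 unchanged genes were called. A list of 25 genes shifted by 1.1-fold was called, and 0 of 28 unshifted lists were called. The simulation held no correlation between genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.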

Results

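Gene expression was measured in the dissected hippocampus of male C57BL/6J mice that had been kept awake for 5 h by gentle handling in the home cage, and in time-matched mice that were left undisturbed. The RNA of each animal was hybridised to its own Affymetrix mouse expression array, a platform on which a transcript is read by 1 or more sets of short probes. There were 8 sleep-deprived and 9 undisturbed animals, 17 arrays in all. The comparison addressed which hippocampal transcripts differ after 5 h of being kept awake by gentle handling. No group was handled for those 5 h and allowed to sleep, so sleep loss and the handling itself cannot be told apart. Array medians lay between 6.13 and 6.22 on the log2 scale, and 18193 genes were tested, each through its brightest probe set. The number of arrays limits the precision of every value below, and all differences are sleep-deprived minus undisturbed on the log2 scale.

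After sleep deprivation 9 of 29 immediate early genes, 7 of 25 glucocorticoid-responsive genes and 6 of 29 endoplasmic reticulum chaperone and stress genes rose and none fell. In the other direction 5 of 21 cholesterol genes fell and 1 rose, and 6 of 28 potassium channel genes fell. As groups these 5 lists passed camera at its preset correlation and not at an estimated one (adjusted p = 0.28 to 0.34). Fos, a transcription factor gene induced within minutes of neuronal activity, rose from 7.41 ± 0.35 (SD, n = 9) to 8.14 ± 0.29 (SD, n = 8), a 1.67-fold difference (log2 difference 0.74, SE 0.13, adjusted p = 0.0025). Arc, which encodes a synaptic protein of activated neurons, rose 1.58-fold (0.66, SE 0.11, adjusted p = 0.0014). Cirbp, a cold-inducible RNA-binding protein gene, fell from 9.16 ± 0.14 (SD, n = 9) to 8.48 ± 0.26 (SD, n = 8), and was 1.60-fold lower (-0.68, SE 0.087, adjusted p = 0.00016). In limma's test 723 of 18193 genes passed an adjusted p of 0.05, of which 227 were higher and 496 lower after sleep deprivation. The differences were small: the median absolute log2 difference of the 723 genes was 0.23, or 1.17-fold, and 489 of them differed by less than 1.2-fold.

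Among called genes with an established symbol and all 8 sleep-deprived arrays on one side of the undisturbed mean, the 15 largest increases ran from 0.74 for Fos down to 0.39 for Alox12b. They included Tent5a (0.58, SE 0.071), Zmym1 (0.56), Tsc22d3 (0.51), Klf2 (0.50), Hspb1 (0.50), Pglyrp1 (0.49), Hspa5 (0.48, SE 0.060) and Nostrin (0.41, SE 0.048). H3c4, Ppp1r3g, Sox11 and Thbs4 completed that group, at 0.43, 0.40, 0.40 and 0.40, of which H3c4 and Ppp1r3g did not pass an unequal-variance test (adjusted p = 0.069 and 0.057). The 15 largest decreases ran from -0.68 for Cirbp to -0.42 for Cobll1. Mfsd4a (-0.58), Wnt9a (-0.56), Usp2 (-0.53), Dbp (-0.50), Krt12 (-0.48) and Hecw2 (-0.48) were among them, with Mansc1 (adjusted p = 0.0996 in an unequal-variance test), Armcx5 and Sytl2 at -0.46, -0.45 and -0.43. Chpf2 (-0.46), Lss (-0.45), Il1rap (-0.44), Filip1 (-0.43) and Cobll1 each had at least 1 further probe set that was dimmer, did not pass the test and had the opposite sign. Mfsd4a and Wnt9a each had a dimmer probe set of the same sign that did not pass, at -0.022 and -0.13. Each differed from the brightest (limma, adjusted p of the difference = 0.015 and 0.039), while 1 other probe set of Mfsd4a passed as lower. With the mean of all probe sets of a gene the calls of Chpf2 (-0.19, adjusted p = 0.074), Il1rap (-0.084, adjusted p = 0.21) and Cobll1 (-0.20, adjusted p = 0.064) were lost, and those of Lss and Filip1 held (adjusted p = 0.034 and 0.030). In 133 of the 18193 tested genes the 2 groups of arrays did not overlap at all, where chance would separate 0.0082% of genes, and 130 of these were called.

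**Figure D1:**
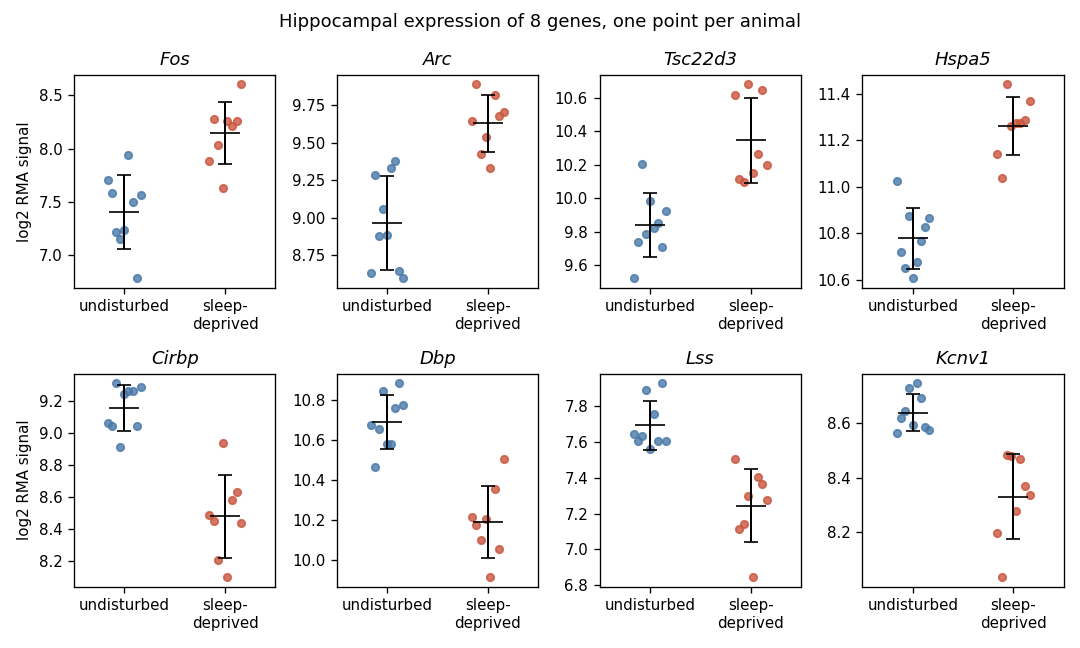
Log2 signal of 8 genes in each animal (points), with group means and standard deviations (bars), for 9 undisturbed and 8 sleep-deprived mice. Fos, Arc, Tsc22d3 and Hspa5 were higher after sleep deprivation, with differences from 0.48 to 0.74, and Cirbp, Dbp, Lss and Kcnv1 were lower, with differences from -0.68 to -0.31.

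Of the 29 measured immediate early genes, the earliest transcripts induced by synaptic activity, 9 rose, none fell and 20 did not pass the test. Adjusted over the list alone, 12 rose. Besides Fos and Arc, these included the nuclear receptor gene Nr4a1 (0.35, adjusted p = 0.0070) and the phosphatase gene Dusp1 (0.27, adjusted p = 0.014). Egr1 (0.10, adjusted p = 0.50) and Npas4 (0.16, adjusted p = 0.47) did not pass. The list stood above other genes in camera (adjusted p = 5.4e-09 with the preset correlation, adjusted p = 0.28 with an estimated correlation). Its mean was higher in all 8 sleep-deprived animals than the undisturbed mean, by 0.17 (two-sided exact permutation test over the 17 arrays, adjusted p = 0.0024). Of 23 delayed plasticity genes, which follow activity by hours, Inhba (0.28) and Gpr3 (0.19) rose, adjusted over the list alone 3 rose and 2 fell, and the list as a whole did not differ (camera adjusted p = 0.81; median -0.0076, mean 0.0070). Inhba did not pass an unequal-variance test (adjusted p = 0.061). Bdnf was at -0.10 (adjusted p = 0.32).

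Homer1, a postsynaptic scaffold gene of the delayed plasticity list with 6 probe sets here, gave different answers by probe set. It entered that list through its brightest probe set only. That probe set, on which the gene-level value rests, did not differ (0.018, adjusted p = 0.87). A dimmer probe set was 2.08-fold higher after sleep deprivation (1.05, SE 0.094, adjusted p over all probe sets = 7.3e-06), the smallest p of the 45037 probe sets tested. The dimmest was also higher (0.48, SE 0.070, adjusted p over all probe sets = 0.00068), and the other 3 lay between -0.0077 and 0.086 and did not pass.

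**Figure D2:**
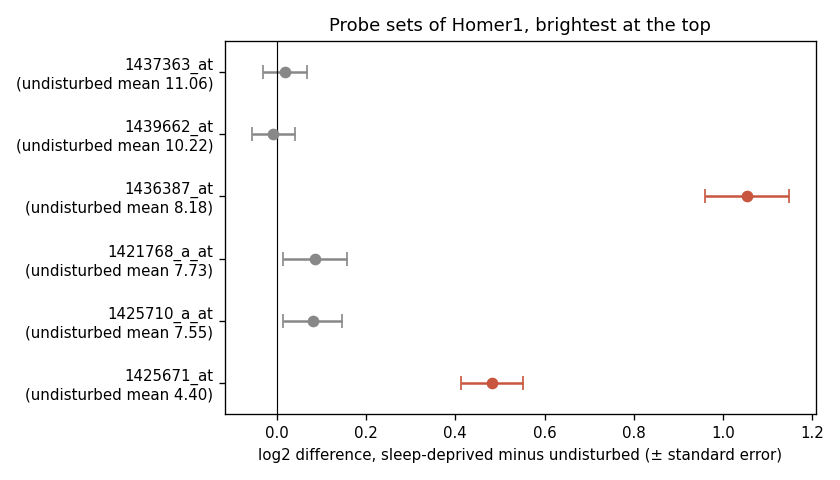
Log2 difference, sleep-deprived minus undisturbed, with its standard error for each of the 6 probe sets of Homer1, ordered by brightness. The 2 probe sets in red, at 1.05 and 0.48, passed an adjusted p of 0.05 over all probe sets.

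Glucocorticoid-responsive genes formed the list with the smallest camera p. Of 25 measured members 7 rose, none fell and 18 did not pass, and 13 rose when adjusted over the list alone. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose by 0.51 (adjusted p = 0.0033), Gjb6 by 0.36 (adjusted p = 0.0082), Ddit4 by 0.30 (adjusted p = 0.023) and Tiparp by 0.28 (adjusted p = 0.0028). Ddit4 lost its call in an unequal-variance and an exact rank-sum test (adjusted p = 0.095 and 0.073), and Tiparp with its most variable probe set (adjusted p = 0.065). Sgk1, a kinase gene of the same response, was 0.52 higher with a wide spread between animals and missed the threshold (adjusted p = 0.054; lowest without 1 array, 0.019), and Fkbp5 was at 0.15 (adjusted p = 0.21). The camera adjusted p was 2e-10, and adjusted p = 0.28 with an estimated correlation. The list mean was higher by 0.21, on the same side in all 8 sleep-deprived animals (exact permutation, adjusted p = 0.0074).

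Of 29 endoplasmic reticulum chaperones and genes of the unfolded protein response 6 rose, none fell and 23 did not pass, 7 of the 29 having negative differences. Adjusted over the list alone 8 rose. Hspa5, the principal chaperone of the compartment, rose 1.40-fold, from 10.8 ± 0.13 (SD, n = 9) to 11.3 ± 0.13 (SD, n = 8) (adjusted p = 0.00015). Manf (0.39), Creld2 (0.36) and Pdia6 (0.33) were among the others. The list differed in camera (adjusted p = 1.2e-05, and adjusted p = 0.28 with an estimated correlation) and in its mean, which was 0.10 higher and above the undisturbed mean in 7 of 8 animals (exact permutation, adjusted p = 0.0074). Of 25 cytosolic heat shock proteins 4 rose, 5 when adjusted over the list alone: Hspb1 (0.50, adjusted p = 0.0020), Chordc1 (0.25, adjusted p = 0.019; 0.064 in an unequal-variance test), Ahsa2 (0.18) and Dnajb4 (0.15). The last pair passed narrowly and lost the call without any 1 of 7 arrays for Ahsa2 (up to an adjusted p of 0.065) and 13 arrays for Dnajb4 (up to 0.089). Hspa1b was at -0.024 (adjusted p = 0.90). Hspa4 was at -0.031 through its brightest probe set (mean level 9.95, adjusted p over all probe sets = 0.88). A dimmer Hspa4 probe set (mean level 9.36) was lower by 0.29 (adjusted p over all probe sets = 0.026). The 2 differed (limma, adjusted p of the difference = 0.014). The list gave a camera adjusted p of 0.0013, and adjusted p = 0.46 with an estimated correlation, and its mean was 0.076 higher (exact permutation, adjusted p = 0.024).

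Among 22 clock genes and clock outputs, 2 rose and 4 fell, and 2 rose and 6 fell when adjusted over the list alone. Dbp and Usp2, both rhythmic outputs of the clock, fell by 0.50 and 0.53 (adjusted p = 0.00031 and 0.00047), while Nfil3, a repressor that binds the same DNA element as Dbp, rose by 0.35 (adjusted p = 0.0022). Tef rose by 0.22 through its brightest probe set (adjusted p = 0.0050), and 1 of its 2 other probe sets had the opposite sign without passing (mean of all probe sets, 0.10, adjusted p = 0.15). Cry2 (-0.18) and Ciart (-0.22) also fell, and lost their calls without any 1 of 14 and 9 arrays (adjusted p up to 0.099 and 0.071). Per1 (0.16, adjusted p = 0.28) and Per2 (0.0097, adjusted p = 0.97) did not pass. The list as a whole did not pass (camera adjusted p = 0.11; 0.049 to 0.25 without 1 array, passing without undisturbed replicate 5 or sleep-deprived replicate 1).

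Of 30 cold-inducible and splicing RNA-binding protein genes, 5 fell and none rose. Adjusted over the list alone 4 rose and 5 fell. With Cirbp these were Hnrnpdl (-0.31, adjusted p = 0.00025), Srsf5 (-0.31, adjusted p = 0.0020), Srsf6 (-0.23) and Hnrnpd (-0.23). The calls of Srsf6 and Hnrnpd were lost without any 1 of 9 and 11 arrays (adjusted p up to 0.075 and 0.082). Another Srsf6 probe set was nearly as bright (mean level 10.02 against 10.18) and lay at 0.13 without passing. It differed from the brightest (limma, adjusted p of the difference = 0.0066). The list passed camera narrowly (adjusted p = 0.048, and adjusted p = 0.66 with an estimated correlation), and not without any 1 of 9 arrays (adjusted p up to 0.19). Its median of -0.043 lay at the 33.9 percentile of 10000 random lists matched on signal level, and its mean did not differ by exact permutation (adjusted p = 0.24).

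Cholesterol synthesis and uptake was the list with the smallest exact permutation p, together with the immediate early genes and the ubiquitin list after adjustment. Of 21 measured members 5 fell, 1 rose and 15 did not pass, and 9 fell and 1 rose when adjusted over the list alone. Lss, which closes the sterol ring, fell by 0.45 (adjusted p = 0.0015), the regulator gene Insig1 by 0.27 (adjusted p = 0.010), Hmgcs1 by 0.21 (adjusted p = 0.016), Mvd by 0.19 (adjusted p = 0.037) and Nsdhl by 0.16 (adjusted p = 0.038). With the mean of all probe sets the calls of Hmgcs1 and Mvd were lost (adjusted p = 0.097 and 0.061). The calls of Mvd and Nsdhl were lost without any 1 of 12 and 10 arrays (adjusted p up to 0.075 and 0.072). Ebp, a sterol isomerase gene, went the other way (0.14, adjusted p = 0.032), and its call was lost without any 1 of 6 arrays (adjusted p up to 0.064). Sc5d did not pass through its brightest probe set (-0.084, mean level 9.53, adjusted p over all probe sets = 0.31). A dimmer Sc5d probe set (mean level 8.88) was higher by 0.22 (adjusted p over all probe sets = 0.029). The 2 differed (limma, adjusted p of the difference = 0.0047). The list mean was lower in all 8 sleep-deprived animals, by a log2 difference of -0.11 (exact permutation, adjusted p = 0.0024; camera adjusted p = 1.5e-05, and adjusted p = 0.28 with an estimated correlation).

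Potassium channel genes fell in 6 of 28 cases and rose in none, and 9 fell when adjusted over the list alone. Kcnj3 (-0.32, adjusted p = 0.0053), Kcnv1 (-0.31, adjusted p = 0.0029), Kcna4 (-0.24, adjusted p = 0.015) and Kcnk2 (-0.20, adjusted p = 0.018) were among them, and Kcnj3 lost its call with the mean of all probe sets (adjusted p = 0.10). The list mean was lower in all 8 animals (-0.095, exact permutation, adjusted p = 0.012; camera adjusted p = 5.6e-05, and adjusted p = 0.34 with an estimated correlation). Of 16 inhibitory synapse genes 2 fell, the receptor subunit genes Gabra4 (-0.29, adjusted p = 0.0029) and Glra2 (-0.35, adjusted p = 0.032), and 4 fell and 1 rose adjusted over the list alone. Glra2 lost its call without any 1 of 7 arrays (adjusted p up to 0.063). This list passed camera (adjusted p = 0.0014, and adjusted p = 0.46 with an estimated correlation) and missed the threshold by exact permutation of its mean (-0.11, adjusted p = 0.063), which it passed after cyclic loess (-0.077, adjusted p = 0.035). Of 29 excitatory synapse genes only Nlgn3 fell (-0.24, adjusted p = 0.022; mean of all probe sets, adjusted p = 0.30), 1 also adjusted over the list alone, Gria1 was at -0.017 (adjusted p = 0.91), and the list did not pass (camera adjusted p = 0.11; 0.034 to 0.43 without 1 array, passing in 4 of 17 cases).

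In the ubiquitin and proteasome list 24 of 26 members had negative differences, yet Usp2, a deubiquitinase gene also held by the clock list, was the 1 member that passed, with 4 adjusted over the list alone. The list mean was -0.087 (exact permutation, adjusted p = 0.0024; camera adjusted p = 5.9e-05, and adjusted p = 0.34 with an estimated correlation). It was -0.050 after quantile normalization or cyclic loess, and the list median of -0.065 lay at the 3.2 percentile of the matched random lists. Of 30 genes of translation initiation and mTOR signalling Eif5 fell (-0.18, adjusted p = 0.012; mean of all probe sets, adjusted p = 0.10), with 2 adjusted over the list alone, while Mtor (-0.12, adjusted p = 0.22) and Eif4ebp2 (0.095, adjusted p = 0.38) did not pass, and the list missed the threshold (camera adjusted p = 0.054), which it passed without any 1 of 9 arrays (0.026 to 0.14 over the 17). Of 27 genes of cAMP and protein kinase A signalling, the transcription factor genes Crem (0.31) and Creb1 (0.18) rose and Pde1b (-0.25) and Adcy8 (-0.41) fell, the same number when adjusted over the list alone, and the list did not differ (camera adjusted p = 0.31). Adcy8 lost its call without any 1 of 4 arrays (adjusted p up to 0.056) and in an unequal-variance and an exact rank-sum test (adjusted p = 0.084 and 0.11). Creb1 lost its call with its most variable probe set (adjusted p = 0.24). Pde4d, a phosphodiesterase gene, was at -0.062 (adjusted p = 0.47). Prkab2, a regulatory subunit gene of AMP-activated kinase that was fixed in advance by name, rose by 0.34 (adjusted p = 0.00039).

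Of 27 chromatin-modifying enzymes, Hdac4 rose (0.33, adjusted p = 0.0024) and Hdac9 and Hdac3 fell (-0.36 and -0.22, adjusted p = 0.0055 and 0.020), with 1 higher and 5 lower adjusted over the list alone. Tet3 was at 0.11 (adjusted p = 0.25), and the list did not pass (camera adjusted p = 0.12; 0.049 without sleep-deprived replicate 1). Of 23 inflammatory mediators 1 rose, Nfkbia (0.28, adjusted p = 0.032), which the glucocorticoid list also holds, and 3 rose when adjusted over the list alone. Nfkbia lost its call without any 1 of 8 arrays (adjusted p up to 0.067). That list passed camera (adjusted p = 0.0069, and adjusted p = 0.34 with an estimated correlation) and missed the threshold by exact permutation (mean 0.062, adjusted p = 0.063). Of 25 genes of glycolysis and glucose transport 1 rose, Pfkfb3 (0.27, adjusted p = 0.040), also adjusted over the list alone, and its call was lost without any 1 of 10 arrays (adjusted p up to 0.078). None of 39 respiratory chain genes and none of 35 cytosolic ribosomal protein genes passed in limma, over all genes or adjusted over the list alone. Among the latter Rps20 was at -0.090 through its brightest probe set (adjusted p = 0.36) and passed with the mean of its 4 probe sets (-0.20, adjusted p = 0.028). The fixed ribosomal list held 60 genes, of which only these 35 were measured. Rps16 was read at 3.52 to 4.12 on all arrays, in the range of the dimmest 10th of genes. Camera adjusted p was 0.66 for glycolysis, 0.19 for the respiratory chain and 0.79 for ribosomal proteins. The mean of the glycolysis list was 0.012 (exact permutation, adjusted p = 0.64), -0.0059 with arrays centred on their medians, and 0.041 after cyclic loess, where it passed (adjusted p = 0.011).

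**Figure D3:**
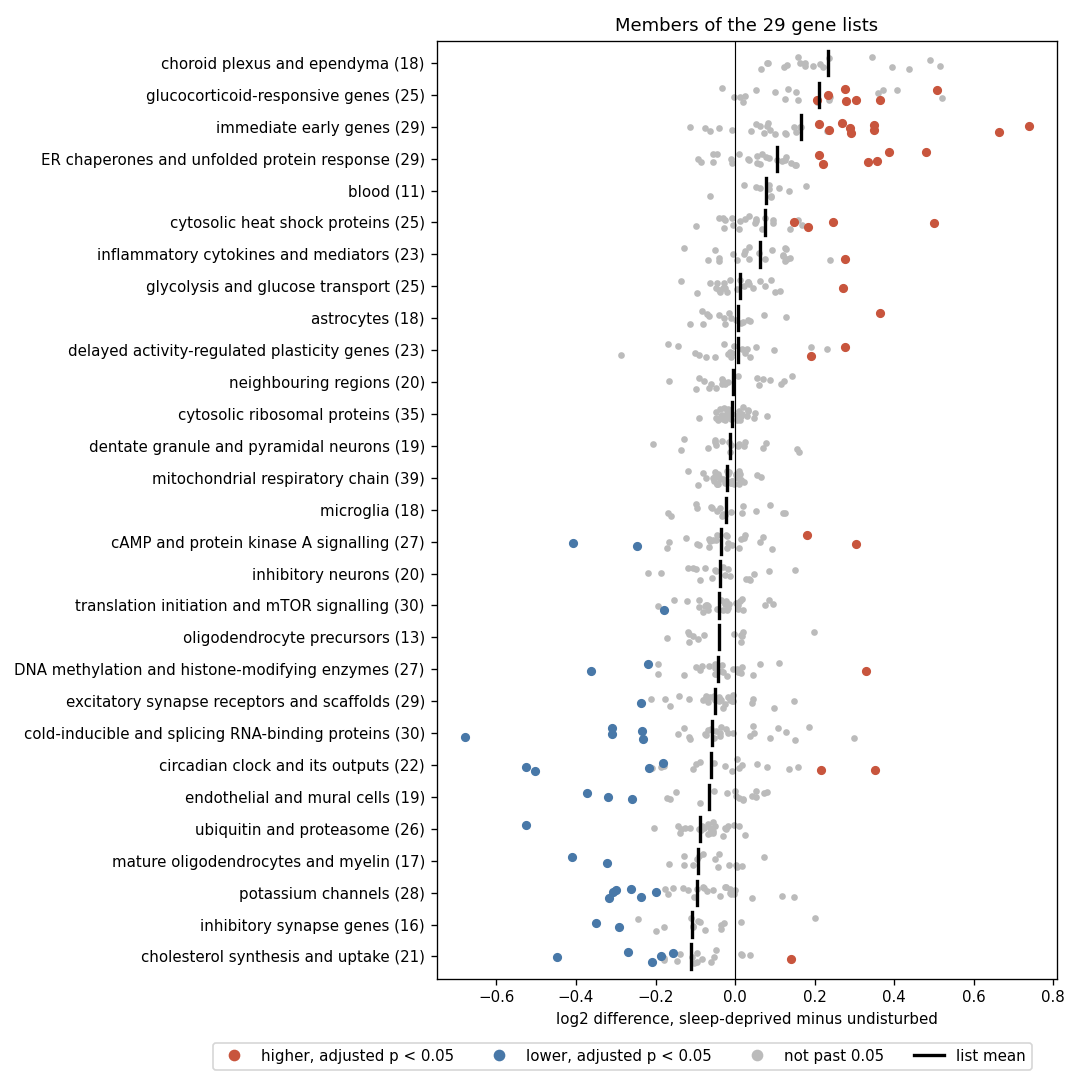
Log2 difference, sleep-deprived minus undisturbed, of each measured member of the 29 gene lists (points, number of members in brackets) and the list mean (black bar). Glucocorticoid-responsive and immediate early genes had means of 0.21 and 0.17, cholesterol genes -0.11, and the 18 choroid plexus markers lay above 0 without any passing the test.

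Of 17 markers of mature oligodendrocytes and myelin, measured in whole hippocampus, Opalin (-0.41, adjusted p = 0.0020) and Aspa (-0.32, adjusted p = 0.0019) fell, 2 also adjusted over the list alone. The myelin list passed camera (adjusted p = 0.0048, and adjusted p = 0.65 with an estimated correlation) but not the exact permutation of its mean (-0.093, adjusted p = 0.18). Of 19 endothelial and mural cell markers the receptor gene Pdgfrb (-0.37, adjusted p = 0.0049), the transporter gene Slco1a4 (-0.32, adjusted p = 0.0057) and Tek (-0.26, adjusted p = 0.040) fell, 3 also adjusted over the list alone. A dimmer probe set of Pdgfrb lay at -0.037 without passing (limma, adjusted p of the difference from the brightest = 0.042). The call of Tek was lost without any 1 of 12 arrays (adjusted p up to 0.080), and the list, with a median of 0.00076 and a mean of -0.065, did not pass (camera adjusted p = 0.11; 0.026 to 0.29 without 1 array, passing without undisturbed replicate 3 or sleep-deprived replicate 5). Gjb6, which the glucocorticoid list holds too, was the 1 astrocyte marker of 18 that rose. No marker of oligodendrocyte precursors, microglia, principal neurons, inhibitory neurons or neighbouring regions passed in limma over all genes, with camera adjusted p values of 0.16, 0.77, 0.98, 0.25 and 0.93, and 0.93 for astrocytes. The astrocyte mean was 0.0079 (exact permutation, adjusted p = 0.83), -0.010 with arrays centred on their medians, and 0.042 after cyclic loess, where it passed (adjusted p = 0.017). Adjusted over the list alone, 1 inhibitory neuron marker was higher and 2 were lower, with 1 call in astrocytes and none in the others. None of 11 blood markers passed singly, although the list passed camera (adjusted p = 0.048, and adjusted p = 0.63 with an estimated correlation; exact permutation of the mean, adjusted p = 0.18) and lost it without any 1 of 8 arrays (adjusted p up to 0.14).

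All 18 measured markers of choroid plexus and ependyma had positive differences, with a list median of 0.19, and none passed, over all genes or adjusted over the list alone. The list passed camera (adjusted p = 0.0018, and adjusted p = 0.65 with an estimated correlation), while exact permutation of its mean gave an adjusted p of 0.46. Ttr, the transthyretin gene that choroid plexus epithelium expresses at very high levels, ranged from 7.12 to 14.3 between animals. It lay above 13 in undisturbed replicates 4 and 9 and in sleep-deprived replicates 3, 5 and 7.

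**Figure D4:**
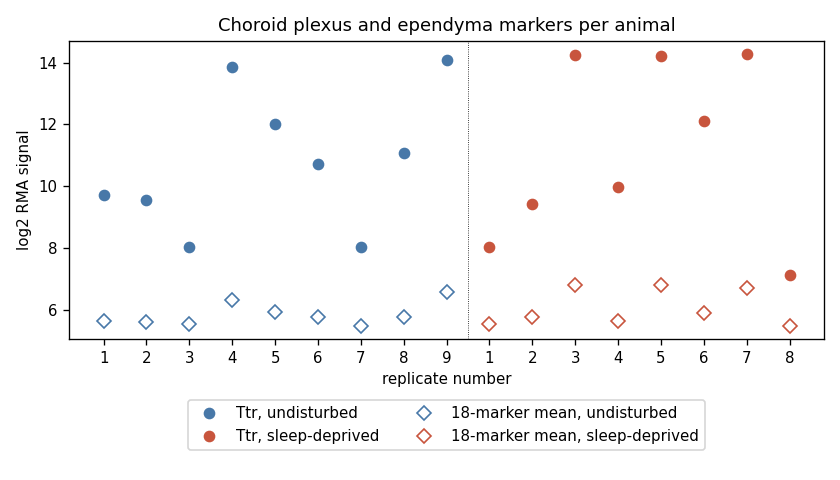
Log2 signal of Ttr (filled circles) and mean of the 18 choroid plexus and ependyma markers (open diamonds) in each of the 9 undisturbed and 8 sleep-deprived animals, by replicate number. Ttr spanned 8.02 to 14.1 in undisturbed and 7.12 to 14.3 in sleep-deprived animals.

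The group difference depended weakly on signal level. In the dimmest 10th of genes the median difference was 0.037, and in the brightest 10th it was -0.038, and the brightest lists above, among them the ubiquitin and ribosomal protein genes, lie where the median is negative. For the dim blood, choroid plexus and inflammatory lists, random lists matched on signal had positive medians of 0.031, 0.028 and 0.014. The medians of these 3 lists lay at the 98.3, 100 and 98.8 percentiles of the matched lists. The gap between the brightest and the dimmest 10th per array averaged 0.034 ± 0.051 (SD, n = 9) in undisturbed and -0.039 ± 0.079 (SD, n = 8) in sleep-deprived animals (two-sided exact permutation, p = 0.036). The split of 227 higher and 496 lower genes became 336 and 390 after quantile normalization, 142 and 621 with arrays centred on their medians and 341 and 432 after cyclic loess, the last chosen after seeing the data. At the level of probe sets 816 of 45037 passed, 263 higher and 553 lower.

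**Figure D5:**
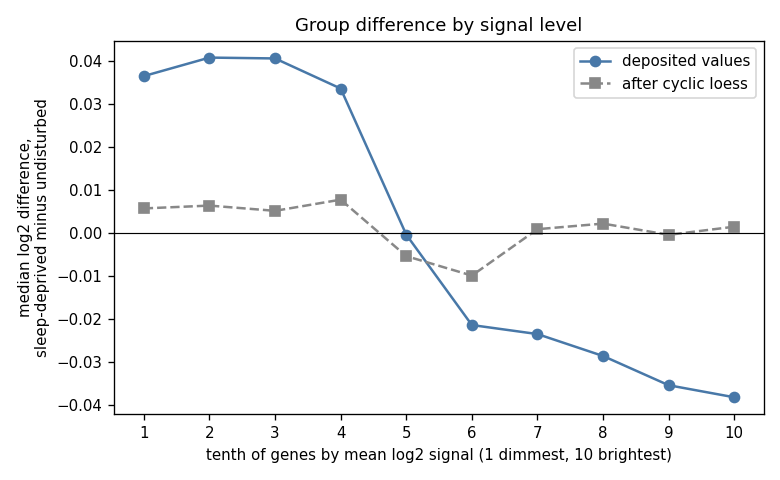
Median log2 difference, sleep-deprived minus undisturbed, in each 10th of the 18193 genes ranked by mean log2 signal, for the deposited values and after cyclic loess normalization between arrays. The deposited values ran from 0.037 in the dimmest to -0.038 in the brightest 10th, and from 0.0058 to 0.0016 after cyclic loess.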

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

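Cyclic loess, the test on the amount of choroid plexus tissue and the splits for single lists were chosen after the results were seen. The RNA integrity covariate was planned. In 236 groups of 8 or 9 values (genes named in the text, array measures and list means) Dixon's test marked 13 values that stood apart, on 8 of the 17 arrays, where chance alone marks about 1 in 20 groups, or 12. The values of Rps16, Sc5d and Hspa4 were not in these groups. Sox11 was lowest in sleep-deprived replicate 5 (9.295), below the other 7 animals of that group. Krt12 was highest in undisturbed replicate 8 (7.125). The gene-level value of Homer1 was highest in undisturbed replicate 1 (11.26). Manf was lowest in undisturbed replicate 2 (9.496). Sleep-deprived replicate 2 was lowest for Crem (7.298). The same animal was lowest for Creb1 (9.618). It was lowest for Glra2 as well (5.506). Rps20 was lowest in that animal too (12.02). Kcna4 was highest in undisturbed replicate 7 (8.002). Kcnk2 was highest in undisturbed replicate 4 (9.903). Hdac9 was lowest in undisturbed replicate 5 (7.879). Hnrnpd was lowest in sleep-deprived replicate 5 (9.755). The 3' minus 5' signal of Gapdh and actin, a measure of RNA integrity, was highest in sleep-deprived replicate 5 (0.4171).

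Among the 64 control probe sets left out of the gene tests, 1 passed in limma when adjusted over the controls, and 11 had an unadjusted p under 0.05. It was the 3' control for the transferrin receptor, with a difference of -0.2518 (adjusted p = 0.049). Of the other 10, 5 were control probe sets for the bacterial gene dap, which mice lack, at -0.22 to -0.35 (adjusted p = 0.085 to 0.25). These differences cannot come from expression of that gene in the animals. They are about as large as the median absolute difference of the called genes, 0.23. Whether a technical difference between the groups bears on the called genes was not tested. The gene of the receptor itself, Tfrc, chosen after its values were seen, fell by 0.36 through its own probe set, lower in 8 of 8 sleep-deprived animals than the undisturbed mean (adjusted p = 0.00019; 3.7e-05 to 0.28 over the alternatives).

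More genes fell (496) than rose (227), and bright genes were lower and dim genes higher as a whole. After cyclic loess, which removes the dependence on signal level, 55.9% of 773 called genes were lower, against 68.6% of 723 before. Without 1 array that share ran from 54.0% to 61.0%, the highest without sleep-deprived replicate 4. Cyclic loess brings the median difference near 0 at every signal level whatever its cause. The fall in the share therefore cannot tell a shift between arrays from a response of the genes. With the RNA integrity measure as a covariate 69.4% of 692 called genes were lower, but without 1 array the share ran from 55.1% to 74.4%. The lowest share was that of 314 genes called without sleep-deprived replicate 5, where the fit without the covariate gave 64.7%. This leaves RNA integrity open. The measure itself was 0.248 in undisturbed and 0.255 in sleep-deprived animals (exact permutation p = 0.868). A change in total RNA per cell also stays open, since the deposited normalization removes it.

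All 18 choroid plexus and ependyma markers had positive differences, with a median of 0.19 (0.11 without sleep-deprived replicate 3, 0.13 without 5 or 7, and up to 0.27 without 4). Cyclic loess kept 90.0% of that median (75.9% to 92.6% without 1 array, the lowest without sleep-deprived replicate 5), which argues against a shift of dim probe sets as the whole cause. The mean of Ttr, Kl, Sostdc1, Clic6 and Kcnj13 was higher by 0.29 (95% interval -0.70 to 1.28, exact permutation p = 0.526), higher than the undisturbed mean in 4 of 8 sleep-deprived animals. These data cannot tell a chance difference in the amount of choroid plexus dissected from a response of that tissue, and a camera p as small was found in 40 of 100 splits of the arrays, the real one included.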

How the results depend on the processing

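Cyclic loess, the first residual component and the exact permutation of list means were chosen after the data were seen. Over the other settings the number of called genes lay within 1.5 times 723, with these exceptions, whose cause was not tested unless given. An unequal-variance test called 467 genes (143 higher, 324 lower). Requiring an adjusted p under 0.01 left 211 (66 and 145), and at least 1.2-fold left 234 (76 and 158), by construction. Centring arrays on their medians gave 142 higher and 621 lower genes, quantile normalization 336 and 390, and cyclic loess 341 and 432. The first residual component, which followed the interquartile range of the arrays (r = -0.834), raised the count to 1237 (411 and 826). Testing only probe sets above the median level gave 1379 called probe sets instead of 816, with fewer tests. Of 29 lists camera called 13, with an estimated correlation 0 (4 at unadjusted p under 0.05), fry 6, exact permutation of list means 7 and, after cyclic loess, 10, which adds inhibitory synapse, glycolysis and astrocytes, and camera on genes above the median level 8. In camera the RNA-binding list was lost by ranks and after quantile normalization or cyclic loess, blood markers after either scaling and with the mean of all probe sets, inflammatory genes with that mean, myelin after cyclic loess, and the RNA-binding, inhibitory synapse and myelin lists above the median level, where choroid plexus and blood markers left fewer than 2 genes and were not tested. Translation and excitatory synapse genes were gained by ranks, and glycolysis after cyclic loess. Without 1 array the counts ran from 481 to 817 genes (150 to 236 higher, 307 to 581 lower), 563 to 889 probe sets and 11 to 17 lists; 481 and 307 were reached without undisturbed replicate 4, 150 without undisturbed replicate 8, and 312 lower genes without sleep-deprived replicate 5. With the most variable probe set of a gene, another probe set is read, and Dnajb4 (-0.1026), Hmgcs1 (0.0008205), Dtna (-0.2461) and Rprd2 (-0.8411) had the opposite sign. The mean of all probe sets ended the calls of Chpf2, Il1rap, Cobll1, Hmgcs1, Kcnj3, Tef, Eif5, Nlgn3, Srsf6, Dnajb4, Mvd and Dtna. The most variable probe set ended those of Tef, Eif5, Ebp, Tiparp, Creb1, Kcnj3, Pfkfb3, Nfkbia, Tek, Hnrnpd, Mvd, Nsdhl, Cry2 and Tfrc. The unequal-variance test ended those of H3c4, Ppp1r3g, Mansc1, Inhba, Chordc1, Srsf6, Ddit4, Adcy8, Nlgn3, Glra2, Pfkfb3, Nfkbia, Tek, Hnrnpd, Mvd, Cry2 and Ciart, and the rank-sum test those of Dnajb4, Srsf6, Ddit4, Adcy8, Glra2, Pfkfb3, Nfkbia, Tek, Hnrnpd, Cry2 and Ciart. Quantile normalization ended those of Srsf6, Tek, Hnrnpd, Mvd, Nsdhl, Cry2 and Ciart, cyclic loess those of Srsf6, Tek, Hnrnpd, Nsdhl and Cry2, median centring those of Ahsa2, Dnajb4, Ebp and Pfkfb3, and array weights those of Glra2, Tek and Nsdhl. The choroid plexus covariate ended those of Ahsa2, Dnajb4, Srsf6, Ebp, Hnrnpd, Mvd, Cry2 and Ciart, and the RNA quality covariate those of Dnajb4 and Cry2. Sgk1 passed in 7 alternatives. In lists without a call, Ndufv1 (respiratory chain) and Dlx1 (inhibitory neurons) passed in 6 each, Reln (inhibitory neurons) and Rps20 (ribosomal proteins) in 2 each, and Lhfpl3 and Gpr17 (oligodendrocyte precursors), C1qc (microglia), Ppp1r1b (neighbouring regions) and Fech (blood) in 1 each. Of 81 called genes in the naming rule or added to it, 67 kept their call whichever array was left out. The values did not settle whether replicate numbers pair the animals. Deviations of same-numbered arrays correlated at -0.159 to 0.393, over 0.1 in 3 of 8 pairs, with a median of 0.0264. For other pairs the median was -0.0182, and 1 sleep-deprived and 2 undisturbed arrays were closest to their own number. A replicate block on 16 arrays called 913 genes, against 640 on the same arrays without the block. It did not call Ebp, Creb1, Pfkfb3, Mvd or Nsdhl. The block called 17 lists, with clock, translation, excitatory synapse and chromatin genes gained. A pairing that the main fit leaves out stays possible. Arrays have no depth, but signal near background compresses differences of dim genes, and in the dimmest 10th of genes 10 were called higher and 2 lower.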

Other observations

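The tests on probe sets of the same gene, their splits of the arrays included, and the splits for single lists were chosen after the result was seen; the splits for the counts of genes, probe sets and lists were planned. With Homer1 included, 189 of 9010 genes with several probe sets had at least 1 whose group difference departed from that of the brightest. These were 217 of 16752 pairs past an adjusted p of 0.05 in limma, with 2348 at an unadjusted p under 0.05. Tested singly over all probe sets, only the brightest passed in 78 of the 217 pairs, only the dimmer in 58, neither in 80 and both in 1. In some pairs the dimmer probe set lay near the lowest signals, at a mean level of 3.38 in 1 of them. Rprd2 was at -0.84 through a dimmer probe set and at 0.030 through its brightest probe set (difference -0.87, SE 0.091, adjusted p = 2.8e-05). Kif1b, a kinesin gene, was at 0.31 through a dimmer probe set and at -0.063 through its brightest (adjusted p of the difference = 0.0032). Dtna, a dystrobrevin gene, fell by 0.25 through a dimmer probe set and rose by 0.23 through its brightest probe set, and was the 1 gene in which both directions passed. Rprd2, Kif1b and Dtna were chosen after their values were seen.

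A candidate explanation is a change in which transcript forms of these genes are made. It is a hypothesis that was not tested here: that would need the position of each probe set in the transcripts, or reads across exon junctions in the same tissue. A compressed response of the dimmer probe set would predict that it mostly changes less, and it did so in 47.5% of the 217 pairs (95% interval 40.7% to 54.3%). In 176 of these pairs the probe sets had opposite signs, where comparing the sizes of the changes does not test compression. Probe sets with the suffix _x_at or _s_at, which can cross-hybridise by design, were in 15.2% of these pairs (10.7% to 20.7%) and 27.4% of all pairs. This argues against them as the main source, and probe sets with other suffixes were not counted. Both intervals treat the pairs as independent, although they came from 189 genes. The highest count of differing pairs in other splits of the arrays was 33, against 217. Unequal probe quality within a gene stays open.

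For the counts of genes and probe sets chance was unlikely, as far as 100 of the 24310 possible splits can show. Of 100 splits of the 17 arrays into 9 and 8, the real one included, 1 gave as many called genes (723, the highest other 15), 1 as many higher genes (227, the highest other 1), 1 as many lower genes (496, the highest other 14) and 1 as many called probe sets (816, the highest other 390). For the number of lists called by camera chance was not excluded: 14 of 100 splits called at least 13, and the highest other called 20. The median over the other splits was 6 lists, so camera's adjusted p at the preset correlation cannot be read as an error rate here. A camera p as small was found in 1 of 100 splits for cholesterol, 2 for endoplasmic reticulum chaperones, 3 for potassium channels, 4 for glucocorticoid-responsive and for inflammatory genes, and 5 for immediate early and for ubiquitin genes. For the other lists that camera called it was found more often: 11 for inhibitory synapse, 14 for heat shock, 22 for myelin, 24 for blood, 38 for RNA-binding protein and 40 for choroid plexus genes.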
